A study of Homo sapiens with 9 samples.

How the data were processed

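Gene expression was measured by RNA sequencing in 9 libraries of the human cell line HAP1, in 3 groups of 3: a control line, a line edited in SENP1 with CRISPR-Cas9 (SENP1-KO) and a line edited in CHD3 in the same way (CHD3-KO). Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, RNA was extracted with the RNeasy Mini kit and turned into stranded poly(A) libraries, and the series text gives paired-end reads of 150 bases. Reads were written with bcl2fastq 2.18.0.12, trimmed with Trimmomatic 0.36 and handled with TopHat2 2.1.1, Cufflinks 2.2.1 and Cuffdiff on the genome build GRCh38, per the submitters' processing notes, which name these tools and give no version for Cuffdiff. The tasks of these tools are those they are commonly used for. The annotation release, the strand setting, the treatment of reads that map to several places and the way the libraries were scaled are not given in the sources used here.

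The values analysed are FPKM (fragments scaled to transcript length and to the mapped total of the library), which the authors deposited for each gene and each replicate in a table of 58288 genes named by Ensembl gene identifiers. The values carry decimals and show no steps of whole reads, so counts cannot be recovered from them and the number of reads behind each value is unknown. Precision was therefore taken from the spread between the 3 libraries of a group, and no interval for counting error could be given. The values of a library summed to between 761745 and 845535 FPKM. An exact 0 in this table can be an estimate that failed: EEF1A1, a widely expressed translation factor, is at 0 in all 9 libraries. Such values are described as listed at 0, and no fold is given against a group listed at 0 in all its libraries. This concerned 30 of the tested genes.

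Identifiers were matched to GENCODE release 29 on GRCh38, which held 58025 of them; 37435 carried a gene symbol of the HUGO nomenclature committee, and genes without such a symbol were tested and counted but not named. Positions, GC content and transcript lengths come from that annotation, which need not be the release the authors used. Among 290 genes that the rule below could name, exons of 50 overlap another gene on the same strand, exons of 113 overlap a gene on the opposite strand, and 29 have a copy of at least 95% identity over at least 300 bases, found by aligning transcripts with minimap2 2.31. Without the strand setting, reads of overlapping genes cannot be told apart, so the values of these genes are uncertain, and they are pointed out in the text.

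Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, which left 12952 genes. Values were put on the log2(FPKM + 0.5) scale, and all fold changes are on that scale, which understates the change of genes with low values. A linear model with the 3 groups was fitted to all 9 libraries with limma 3.58.1 (trend on the mean, not robust) in R 4.3.3, so that the groups share an estimate of the spread. Moderated tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The comparisons were SENP1-KO with control, CHD3-KO with control and SENP1-KO with CHD3-KO, together with an F test over the 3 groups. The targeted genes were also tested with an exact two-sided permutation test, whose smallest possible p for 3 against 3 libraries is 0.1. The p-values measure the spread between these libraries, and the labels do not say how many edited clones stand behind a group. Tables and figures were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

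Gene lists (58, covering complexes, pathways, stress responses, metabolism and markers of cell types) were written down from general knowledge, and 53 had at least 5 tested members. Each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 53 lists. The same test with an estimated correlation and fry served as alternatives. The fry p asks whether the members of a list move on balance in 1 direction, its mixed p asks whether they change in either direction, and neither compares a list with other genes. Counts of members past the threshold are given over all tested genes and adjusted over the list alone.

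The genes named in the text follow a rule. It takes SENP1 and CHD3, then, for each comparison with control, the 12 higher and the 12 lower genes with the largest absolute log2 change among those past the threshold whose higher group has a mean of at least 5 FPKM and whose 3 libraries do not overlap those of the other group. It further takes 6 and 6 genes by the same rule for the knockouts against each other, 10 genes changed in the same direction in both knockouts, 6 changed in opposite directions, and up to 4 members past the threshold per gene list. Genes without a symbol, joined symbols, Y-linked genes and XIST were left out. The text prints part of these genes, and says where a gene outside the rule is given. Lists, tests, the rule and most alternatives were fixed before the data were examined.

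The steps were tested on simulated data with 200 genes changed among 12952. For SENP1-KO against control, 58.5%, 83.3% and 95.7% of the changes of 1.5, 2 and 4 fold were recovered, with 8 false calls among 167. For CHD3-KO against control the shares were 52.9%, 85.5% and 98.6%, with 7 false calls among 165. In these simulated data each gene varied on its own, with no trend across genes. The shares and false calls therefore need not hold for the real libraries. Because both knockouts were compared with the same 3 control libraries, all 3 groups were simulated 100 times without change, to give the overlap and correlation that arise with no effect.

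Results were recomputed with pseudocounts of 0.1 and 1, without a filter, with a mean of at least 5 FPKM, after median-ratio scaling and after quantile normalization, with robust moderation, with a fit over the 6 libraries of a comparison, with the replicate number as a block, with a minimum 2-fold change, and without each library in turn. Some alternatives were chosen after seeing the data: removal of the trend with GC content and transcript length from each library, protein-coding genes only, and removal of the 30 genes listed at 0 in a whole group. No columns of the table were left unused.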

Results

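Poly(A) RNA was sequenced from HAP1 cells of 3 kinds: a control line, a line in which SENP1 had been knocked out with CRISPR-Cas9, and a line with a CHD3 knockout. HAP1 is a near-haploid human line that goes back to a chronic myelogenous leukaemia, which makes single-allele edits sufficient for a knockout. SENP1 is a protease that matures the small protein SUMO and removes it from its targets. CHD3 is an ATP-dependent chromatin remodeller of the NuRD complex, which also carries histone deacetylases. Each group had 3 libraries, which the series text calls biological replicates. Expression was given as FPKM, and the number of reads per library is unknown. The values of a library summed to between 761745 and 845535 FPKM, with 12285 to 12624 genes at 1 FPKM or more. Pearson's r of the log2 values across genes, which are not independent replicates, was 0.976 to 0.985 between libraries of the same group and 0.943 to 0.976 between libraries of different groups. The median SD of a gene over the 3 libraries was 0.13 in control, 0.12 in SENP1-KO and 0.17 in CHD3-KO on the log2 scale. The first principal component (43% of the variance) placed SENP1-KO at one end and CHD3-KO at the other, with the control libraries between them, and the second (18.7%) separated control from both knockouts.

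The targeted genes were examined before any other. SENP1 (ENSG00000079387, GRCh38 chromosome 12: 48042898 to 48106308, minus strand) measured 14.2 ± 0.725 FPKM in SENP1-KO, 20.1 ± 1.56 in control and 20.2 ± 2.177 in CHD3-KO (mean ± SD, n = 3 each). Its log2 change against control was -0.48 (SE 0.10, limma adjusted p = 0.0118; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries can give). Without SENP1-KO replicate 2 the log2 change was -0.45 and the limma adjusted p 0.054, the highest of the 21 alternatives, whose lowest was 0.00549. SENP1 shares exon sequence with PFKM on the opposite strand. CHD3 (ENSG00000170004, chromosome 17: 7884806 to 7912760, plus strand) measured 26.7, 50.7 and 26.4 FPKM in the CHD3-KO libraries, 38.8 ± 0.909 in control and 36.8 ± 2.001 in SENP1-KO. Its log2 change in CHD3-KO was -0.23 (SE 0.21, limma adjusted p = 0.69; exact permutation p = 0.4, two-sided). Without the library labelled CHD3-KO replicate 2, in which the CHD3 transcript lay above every control library, the log2 change was -0.54 (limma adjusted p = 0.00816, against up to 0.924 over the other alternatives). An edit that disrupts the reading frame need not lower the amount of transcript, so these levels check the labels only in part. In a check chosen after these values were seen, genes that differed at least 2-fold between CHD3-KO and control were picked by limma without this library. Of these 137 genes, it lay nearer to the other CHD3-KO libraries than to control in 133 and nearer to control in 4.

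The comparison of SENP1-KO with control asks which transcripts differ in cells edited in the SUMO protease gene. Genes typical of epithelial and of pluripotent cells were among those that rose most. CRABP2, a carrier of retinoic acid, rose from 8.82 ± 0.174 to 71.9 ± 8.99 FPKM (n = 3 each; log2 change 2.95, SE 0.12, limma adjusted p = 1.31e-06). The keratin gene KRT8 rose from 3.15 ± 1.59 to 25.8 ± 3.32 FPKM (2.95, SE 0.30, limma adjusted p = 0.00039). LIN28A, which encodes an RNA-binding protein of pluripotent stem cells (chromosome 1: 26410778 to 26429722), rose from 7.25 ± 1.19 to 53.9 ± 7.14 FPKM (2.82, SE 0.15, limma adjusted p = 5.13e-06). CLDN6, a claudin of tight junctions, was near 0 in control (0.0877 ± 0.116 FPKM) and reached 6.43 ± 1.13 FPKM (3.56, SE 0.21, limma adjusted p = 9.32e-06). The actin-binding POF1B rose from 3.77 ± 0.332 to 19.01 ± 0.996 FPKM (2.19, SE 0.10, limma adjusted p = 1.69e-06). Among the genes that fell, PSMB8, a catalytic subunit of the immunoproteasome (chromosome 6: 32840717 to 32844703), went from 7.92 ± 0.745 to 0.298 ± 0.171 FPKM (-3.42, SE 0.17, limma adjusted p = 3.67e-06). GSTM3, a glutathione transferase, fell from 10.2 ± 1.40 to 0.00817 ± 0.00193 FPKM (-4.39, SE 0.14, limma adjusted p = 2.77e-07). The secreted protease HTRA1 fell from 12.996 ± 2.33 to 3.05 ± 0.172 FPKM (-1.91, SE 0.12, limma adjusted p = 1.55e-05). KRT8 and CLDN6 have near-identical copies, and exons of KRT8, CLDN6, PSMB8, GSTM3 and HTRA1 overlap a gene on the opposite strand, so their values are less certain. The plot of 12 named genes shows the 9 libraries for most of these.

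**Figure D1:**
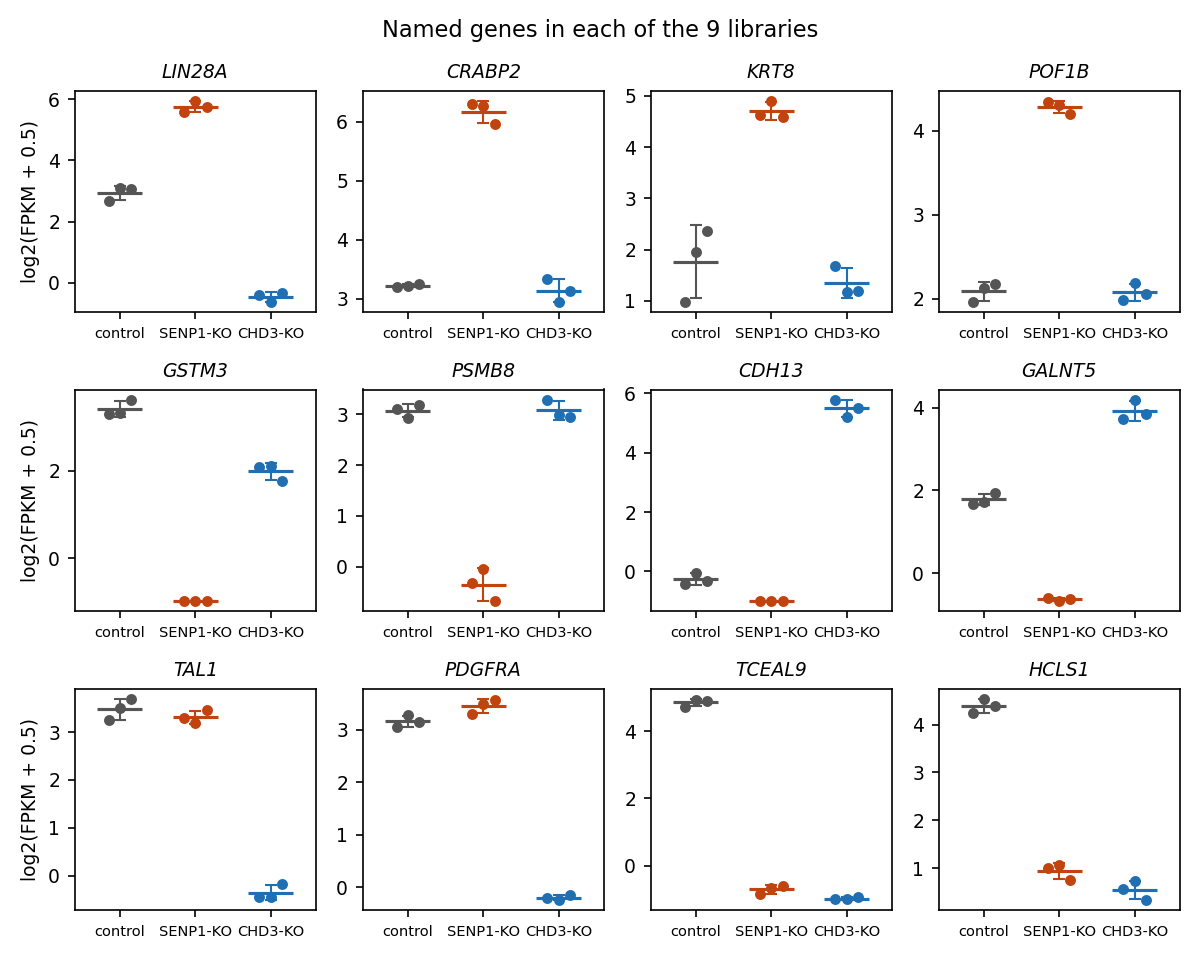
Expression of 12 named genes in each of the 9 libraries, as log2(FPKM + 0.5); points are libraries, horizontal lines the group means and bars the SD (n = 3). LIN28A lay at 53.9 FPKM in SENP1-KO, 7.25 in control and 0.233 in CHD3-KO, and TCEAL9 fell from 28.5 FPKM in control to under 1 in both knockouts.

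Of the 12952 genes tested, 2111 passed the limma test in SENP1-KO, 1407 higher and 704 lower, so that 66.7% were higher. At least 2-fold changes on the log2(FPKM + 0.5) scale were seen in 291 of the higher and 133 of the lower genes, and 4108 genes had an unadjusted p under 0.05. After quantile normalization 1239 were higher and 1058 lower (53.9% higher). With the trend of GC content and transcript length removed, 1045 were higher and 788 lower (57% higher), and 1253 of the 2111 genes were still called. Without SENP1-KO replicate 1 there were 568 higher and 327 lower genes, and without SENP1-KO replicate 2 there were 523 and 293. Without control replicate 1 there were 745 and 394, without control replicate 2 there were 746 and 322, and without control replicate 3 there were 376 lower genes.

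Of the 53 lists tested, 8 passed in SENP1-KO, and 0 did with an estimated correlation. Of the epithelial list, 7 of the 11 tested members rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone. Its median was 0.67 (camera adjusted p = 0.000171, adjusted p = 0.224 with an estimated correlation, and 6.28e-07 at the lowest of its 22 alternatives). Besides KRT8 and CLDN6, these were led by SPINT2, an inhibitor of membrane serine proteases that rose from 9.47 ± 0.949 to 30.4 ± 4.01 FPKM (log2 change 1.63), and by ESRP1, a splicing regulator of epithelial cells that rose from 3.16 ± 0.131 to 10.6 ± 0.304 FPKM (1.61), while the adhesion molecule EPCAM fell (-0.99). In the metallothionein list, which holds small metal-binding proteins, 4 of 5 members rose, and all 5 when adjusted over the list alone. Their median log2 change was 1.41 (camera adjusted p = 0.00135, adjusted p = 0.39 with an estimated correlation, and 0.000157 at the lowest of its 21 alternatives). MT1X rose from 61.5 ± 28.4 to 206 ± 56.0 FPKM and MT2A from 5.08 ± 1.25 to 18.7 ± 5.47 FPKM. Cholesterol synthesis had 24 tested members, of which 6 rose and the other 18 did not pass, with 7 higher when adjusted over the list alone. The list median was 0.19 (camera adjusted p = 0.00322, adjusted p = 0.224 with an estimated correlation, and 7.79e-05 at the lowest). MVD, which makes isopentenyl diphosphate, rose from 7.21 ± 0.544 to 16.5 ± 0.774 FPKM, and LSS, the lanosterol synthase, from 7.71 ± 0.799 to 14.3 ± 2.85 FPKM. Of 10 tested pluripotency genes, 4 rose, LIN28A and the Nodal co-receptor TDGF1 (5.71 ± 0.779 to 18.3 ± 2.26 FPKM, log2 change 1.60) among them, and 4 when adjusted over the list alone. The median log2 change was 0.16 (mean 0.55, camera adjusted p = 0.0456, adjusted p = 0.357 with an estimated correlation, the highest over its alternatives, and 0.000459 the lowest, which was given by fry). Without control replicate 2 its camera adjusted p was 0.0529, without CHD3-KO replicate 3 it was 0.0535, and with protein-coding genes only 0.0682. SPINT2, MT1X and TDGF1 overlap another gene on the same strand, LSS and TDGF1 overlap a gene on the opposite strand, and EPCAM and TDGF1 have a near-identical copy.

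GC content moved with this comparison. Over the 12918 tested genes with a GC value, which are not independent replicates, the log2 change correlated with GC content at Pearson's r = 0.44 and Spearman's rho = 0.49, and its median was -0.11 in the fifth of genes with the lowest GC content and 0.37 in the fifth with the highest. The slopes per 10 points of GC were 0.23, 0.16 and 0.06 in the SENP1-KO libraries, -0.05, -0.10 and -0.10 in control and 0.06, -0.18 and -0.09 in CHD3-KO. Beside this stand groups with smaller median changes. The nuclear genes of oxidative phosphorylation, the mitochondrial respiratory chain, had 76 tested members, of which 16 rose and 1 fell, with 20 and 2 when adjusted over the list alone. The median of the list was 0.11 (camera adjusted p = 0.0456, adjusted p = 0.459 with an estimated correlation, the highest over its alternatives, and 0.00692 the lowest). NDUFA11 of complex I rose from 14.4 ± 6.74 to 43.4 ± 9.80 FPKM and NDUFA7 from 17.3 ± 3.94 to 46.5 ± 9.53 FPKM, and exons of both overlap other genes on either strand. The camera adjusted p of this list was 0.0252 with the GC trend removed, 0.133 without control replicate 2, 0.0585 without SENP1-KO replicate 2 and 0.0535 without CHD3-KO replicate 3. It was 0.118 after quantile normalization, 0.0555 after median-ratio scaling and 0.0697 with protein-coding genes only. Mitochondrial ribosomal proteins had 18 members higher and the other 58 of 76 not past the test, with 23 higher when adjusted over the list alone. Its median was 0.10 (camera adjusted p = 0.0303, adjusted p = 0.459 with an estimated correlation, the highest over its alternatives, and 0.00239 the lowest). MRPL54 rose from 23.4 ± 2.995 to 51.0 ± 9.19 FPKM and MRPS23 from 37.2 ± 8.44 to 73.6 ± 11.5 FPKM. This list was at 0.045 with the GC trend removed, 0.0529 without control replicate 2, 0.0683 after quantile normalization and 0.0682 with protein-coding genes only.

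A pair of further lists passed and lost the call once the GC trend was removed. Zinc finger genes with ZNF symbols, most of which encode DNA-binding proteins, had 27 of 371 members lower and 13 higher, with 18 and 8 when adjusted over the list alone. Their median log2 change was -0.09 (camera adjusted p = 0.0262, adjusted p = 0.708 with an estimated correlation, the highest over its alternatives, and 0.00448 the lowest). Their camera adjusted p was 0.14 with the GC trend removed and 0.0529 without control replicate 2, and with fry the adjusted p was 0.15. ZNF704 fell from 1.51 ± 0.937 to 0.179 ± 0.0610 FPKM (log2 change -1.46). Axon guidance genes had 10 of 37 members higher and 3 lower, with 13 and 4 when adjusted over the list alone. The list median was 0.35 (camera adjusted p = 0.0303, adjusted p = 0.357 with an estimated correlation, and from 0.00866, which was given by fry, to 0.502 over all alternatives). The camera adjusted p was 0.257 with the GC trend removed, 0.0525 without control replicate 2, 0.056 with protein-coding genes only and 0.502 with a mean of at least 5 FPKM. Of the members that rose, the ephrin receptor genes EPHA7 (5.77 ± 1.71 to 13.7 ± 1.55 FPKM, log2 change 1.21) and EPHA3 (12.3 ± 0.936 to 19.6 ± 1.38 FPKM, 0.65) are among the named genes. The 3 members that fell were the secreted guidance cues SEMA3A (4.001 ± 1.14 to 0.633 ± 0.357 FPKM, log2 change -2.003) and SLIT2 (6.57 ± 0.578 to 2.48 ± 0.273 FPKM, -1.25) and the semaphorin receptor PLXNC1 (9.30 ± 0.867 to 3.77 ± 0.399 FPKM, -1.20), which overlaps a gene on the opposite strand.

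Of the 27 tested genes of the SUMO pathway list, which does not hold SENP1, 2 rose and the other 25 did not pass. When adjusted over the list alone, 2 were higher. The list's median was -0.04, its mean 0.03 and its camera test pointed down (adjusted p = 0.758), so these differ in sign. SUMO2 rose from 293 ± 18.3 to 397 ± 19.8 FPKM (log2 change 0.44, SE 0.08, limma adjusted p = 0.00669) and shares exon sequence with JPT1. RNF4, a ubiquitin ligase that binds SUMO chains and has a near-identical copy and overlapping neighbours, rose by 0.68 (limma adjusted p = 0.0161). Over 21 alternatives its p ran from 0.00248 to 0.0686 (0.0512 with no filter, 0.0515 without control replicate 1, 0.0501 without SENP1-KO replicate 1 and 0.0686 without SENP1-KO replicate 2). Genes of the immediate-early response, which serum and growth factors induce, had 7 of 27 members lower and 1 higher, and the list did not pass (camera adjusted p = 0.0837). EGR1 fell from 51.0 ± 3.63 to 18.5 ± 2.77 FPKM, JUN from 7.09 ± 2.15 to 2.27 ± 0.239 FPKM and FOSB from 8.24 ± 1.73 to 3.08 ± 0.608 FPKM.

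The comparison of CHD3-KO with control asks which transcripts differ in cells edited in the NuRD remodeller gene. CDH13, which encodes the membrane-anchored T-cadherin (chromosome 16: 82626803 to 83800640), rose from 0.337 ± 0.1202 to 45.2 ± 9.30 FPKM (n = 3 each; log2 change 5.76, SE 0.17, limma adjusted p = 3.45e-08). GALNT5, a glycosyltransferase that starts O-linked sugar chains, rose from 2.95 ± 0.334 to 14.8 ± 2.65 FPKM (2.14, SE 0.14, limma adjusted p = 2.15e-05). CAPN6, a calpain family member, rose from 3.03 ± 0.866 to 17.5 ± 4.52 FPKM (2.35, SE 0.20, limma adjusted p = 0.000127). Several regulators expressed in control were near 0. TAL1, a transcription factor of blood stem cells (chromosome 1: 47216290 to 47232220), fell from 10.8 ± 1.69 to 0.286 ± 0.0890 FPKM (-3.84, SE 0.14, limma adjusted p = 1.7e-07). CGAS, the sensor of DNA in the cytosol, fell from 8.01 ± 0.893 to 0.0313 ± 0.0105 FPKM (-3.997, SE 0.13, limma adjusted p = 4.94e-08). The growth factor receptor PDGFRA fell from 8.42 ± 0.694 to 0.374 ± 0.0282 FPKM (-3.35, SE 0.11, limma adjusted p = 7.65e-08). The ephrin receptor EPHA3 fell from 12.3 ± 0.936 to 0.818 ± 0.0845 FPKM (-3.28, SE 0.10, limma adjusted p = 3.69e-08) and LIN28A from 7.25 ± 1.19 to 0.233 ± 0.0798 FPKM (-3.40, SE 0.15, limma adjusted p = 5.59e-07). CDH13, TAL1 and CGAS overlap a gene on the opposite strand and PDGFRA a gene on the same strand.

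In the library labelled CHD3-KO replicate 2 the CHD3 transcript lay above all controls. In all, 321 genes passed the limma test in CHD3-KO, 174 higher and 147 lower, of which 58 and 97 changed at least 2-fold, and 1810 genes had an unadjusted p under 0.05. Without control replicate 1 there were 101 higher and 101 lower genes, and without control replicate 2 there were 77 higher and 76 lower. Without control replicate 3 there were 97 and 71, without CHD3-KO replicate 3 there were 96 higher and 124 lower, and without the library labelled CHD3-KO replicate 2 there were 97 and 116. The balance also turned to more lower than higher genes with no filter (146 higher and 179 lower), after median-ratio scaling (158 and 168) and quantile normalization (159 and 164), in the fit over 6 libraries (109 and 112) and with the GC trend removed (234 and 243), so neither direction prevailed throughout. The mitochondrially encoded genes MT-ATP8, MT-ATP6 and MT-CO3 were listed at 0 in all 3 CHD3-KO libraries, while MT-ATP8 stood at 44955, 40886 and 45233 FPKM in control. The other 10 mitochondrially encoded protein genes had a median log2 change of 0.24, with 0.193 as the lowest limma adjusted p. With these zeros, mitochondrial transcripts made up 12.2 to 14.4% of the FPKM in CHD3-KO, 16.6 to 19.5% in control and 16.8 to 17.1% in SENP1-KO.

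Of the 53 lists, 13 passed in CHD3-KO, and 0 did with an estimated correlation. Pluripotency genes were lower: 3 of 10 members fell and the other 7 did not pass, with 3 lower when adjusted over the list alone. The median log2 change was -0.14 (mean -0.78, camera adjusted p = 1.04e-05, adjusted p = 0.105 with an estimated correlation, and 1.21e-06 at the lowest of its 22 alternatives). Besides LIN28A, these were TDGF1 (5.71 ± 0.779 to 1.504 ± 0.426 FPKM, log2 change -1.64) and GDF3, a ligand related to Nodal (2.182 ± 0.254 to 0.20045 ± 0.0755 FPKM, -1.94). Among 15 tested stem and progenitor cell genes, 4 fell and 1 rose, also when adjusted over the list alone. The median of the list was -0.09 (camera adjusted p = 0.000594, adjusted p = 0.127 with an estimated correlation, and 8.21e-06 at the lowest, which was given by fry). TAL1 led them, with PROM1, which encodes the surface protein CD133 and overlaps a neighbour (5.44 ± 0.205 to 1.73 ± 0.329 FPKM), and the receptor KIT (2.94 ± 0.132 to 1.48 ± 0.0999 FPKM). This list was at 0.0569 with no filter and 0.117 with a mean of at least 5 FPKM. The epithelial list had 3 of 11 members lower and the other 8 not past the test, with 3 lower when adjusted over the list alone. Its median was -0.18 (camera adjusted p = 0.00241, adjusted p = 0.192 with an estimated correlation, and 0.0015 at the lowest). CLDN1 fell from 3.42 ± 0.468 to 0.490 ± 0.0964 FPKM and EPCAM, which has a near-identical copy, from 1.69 ± 0.167 to 0.380 ± 0.099995 FPKM. That list was at 0.0569 with no filter and 0.137 with a mean of at least 5 FPKM.

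Further lists shifted by small amounts in which no single member passed limma's test. The lists of G2/M and mitosis (camera adjusted p = 0.517) and of mitochondrial ribosomal proteins (0.189) did not pass. Ribosome biogenesis genes had lower values in 49 of 53 members, 13 of them with an unadjusted p under 0.05, and 0 passed, also when adjusted over the list alone. Their median log2 change was -0.14 (camera adjusted p = 1.75e-08, adjusted p = 0.192 with an estimated correlation, and 2.76e-10 at the lowest of its 22 alternatives). Genes of G1/S and DNA replication had lower values in 45 of 51 members, 13 of them with an unadjusted p under 0.05, and 0 passed. The list median was -0.16 (camera adjusted p = 3.22e-08, adjusted p = 0.192 with an estimated correlation, and 5.47e-10 at the lowest). Heat shock proteins and chaperones (lower values in 25 of 30, 6 with an unadjusted p under 0.05, 0 past limma's test, median -0.10, camera adjusted p = 0.00609) were at an adjusted p = 0.576 with an estimated correlation, the highest over the alternatives, which began at 0.000384. Without CHD3-KO replicate 1 this list was at 0.0988, and with fry at 0.273. The unfolded protein response (lower values in 23 of 27, 2 lower and 1 higher with an unadjusted p under 0.05, 0 past limma's test, median -0.10, camera adjusted p = 0.0186) was at an adjusted p = 0.391 with an estimated correlation, the highest over the alternatives, which began at 0.00758, and with fry at 0.0744. Higher values were seen in 65 of 82 cytosolic ribosomal proteins, 3 with an unadjusted p under 0.05 and 0 past limma's test. The median log2 change was 0.13 (camera adjusted p = 0.0272, adjusted p = 0.709 with an estimated correlation, the highest over the alternatives, and 0.000764 the lowest). This list was at 0.365 without control replicate 2, at 0.226 without the library labelled CHD3-KO replicate 2 and at 0.21 with fry.

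Smaller lists passed in CHD3-KO at a camera adjusted p of 0.0272, each lost with an estimated correlation. Of 11 tested imprinted genes, which are expressed from a single parental copy in many tissues, 2 rose and the other 9 did not pass, also when adjusted over the list alone. The median of the list was 0.13 (adjusted p = 0.192 with an estimated correlation, the highest over the alternatives, and 0.00538 the lowest). They are neighbours on chromosome 15: the ubiquitin ligase gene UBE3A rose from 43.2 ± 4.32 to 93.7 ± 9.54 FPKM, with a near-identical copy and overlapping genes, and the lipid flippase gene ATP10A from 1.85 ± 0.233 to 4.51 ± 0.960 FPKM. The list was at 0.0512 without control replicate 2, 0.103 without control replicate 3, 0.0722 without CHD3-KO replicate 1, 0.123 with no filter and 0.155 with a mean of at least 5 FPKM. Integrins had 1 of 13 members past the test, ITGB8, which rose from 1.16 ± 0.198 to 3.66 ± 0.178 FPKM (overlapping a gene on the opposite strand; list median 0.21, adjusted p = 0.22 with an estimated correlation, and 0.014 to 0.282 over all alternatives). The list was at 0.0963 without control replicate 1, 0.0546 without control replicate 3, 0.0759 without the library labelled CHD3-KO replicate 2, 0.123 with no filter and 0.282 with a mean of at least 5 FPKM. Fibroblast markers had 1 of 6 members lower, PDGFRA (median -0.21, adjusted p = 0.192 with an estimated correlation, and 2.16e-05, which was given by fry, to 0.225 over all alternatives). They were at 0.0857 without CHD3-KO replicate 3, 0.225 with no filter, 0.0619 after quantile normalization and 0.0644 with the replicate block. Cytoskeletal and contractile genes had 2 of 29 members lower, the smooth muscle actin ACTG2 (16.9 ± 1.02 to 8.23 ± 1.38 FPKM) among them (median -0.14, adjusted p = 0.576 with an estimated correlation, the highest over the alternatives, and 0.00454 the lowest). The list was at 0.0687 without control replicate 2 and 0.226 without the library labelled CHD3-KO replicate 2. It was at 0.272 with no filter, 0.0828 with a mean of at least 5 FPKM, 0.0751 after quantile normalization and 0.21 with fry. Cholesterol synthesis had higher values in 20 of 24 members, 4 with an unadjusted p under 0.05 and 0 past limma's test (median 0.11, adjusted p = 0.192 with an estimated correlation, the highest over the alternatives, and 0.00741 the lowest). It was at 0.098 without control replicate 2 and 0.0602 without CHD3-KO replicate 1. In the NuRD complex list, to which CHD3 belongs, 1 of 17 members passed, and the list did not (camera adjusted p = 0.812). This was ZMYND8, which overlaps a gene on the opposite strand and was higher by 0.75 (limma adjusted p = 0.0448). It passed in 8 of 21 alternatives, with p from 0.000937 to 0.164 (0.115 with no filter, 0.0768, 0.164 and 0.159 without control replicates 1, 2 and 3, 0.0706, 0.0749 and 0.0754 without SENP1-KO replicates 1, 2 and 3, 0.131 without the library labelled CHD3-KO replicate 2 and 0.14 without CHD3-KO replicate 3).

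**Figure D2:**
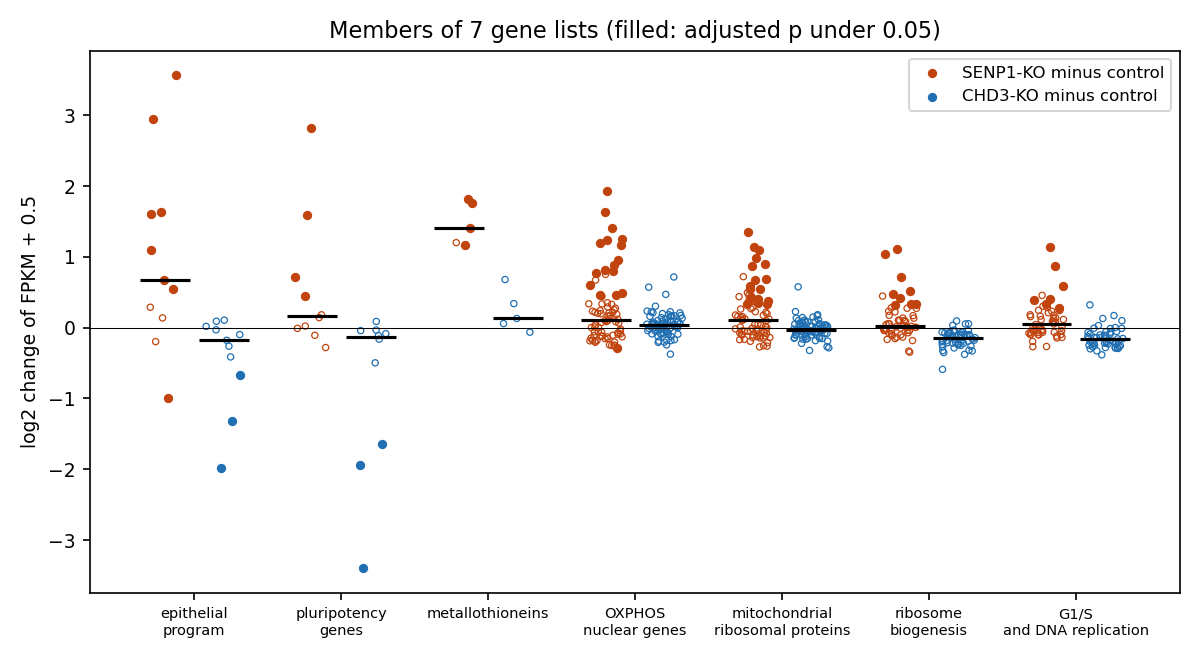
Log2 change of FPKM + 0.5 of each tested member of 7 gene lists, for SENP1-KO and for CHD3-KO against control; filled points passed the limma test and black lines are medians. The epithelial list has a median of 0.67 in SENP1-KO and -0.18 in CHD3-KO, and the 53 ribosome biogenesis genes sit at a median of -0.14 in CHD3-KO with 0 members past the test and 13 lower at an unadjusted p under 0.05.

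The knockouts were also set against each other, and some of the genes that differed, such as LIN28A, had moved in opposite directions from control. LIN28A was higher in SENP1-KO than in CHD3-KO by 6.21 (SE 0.15, limma adjusted p = 5.76e-09, n = 3 each), TMEM47, which encodes a membrane protein of cell junctions, by 5.32 (46.0 ± 2.63 against 0.674 ± 0.177 FPKM; limma adjusted p = 9.13e-09) and ESRG, a long noncoding RNA of pluripotent cells, by 4.46 (14.2 ± 0.437 against 0.165 ± 0.0266 FPKM; limma adjusted p = 3.24e-08). GALNT5 was lower in SENP1-KO (0.144 ± 0.0169 against 14.8 ± 2.65 FPKM, log2 difference -4.56, limma adjusted p = 2.89e-08), and CDH13 was listed at 0 in all 3 SENP1-KO libraries. The library labelled CHD3-KO replicate 2, whose CHD3 transcript lay above all controls, belongs to this comparison too. In total 3627 genes passed the limma test, 1937 higher and 1690 lower in SENP1-KO, of which 308 and 206 differed at least 2-fold. After quantile normalization 1810 were higher and 2080 lower, so the balance of directions turned. Without SENP1-KO replicate 1 these counts were 1160 and 1025, without SENP1-KO replicate 2 they were 1021 and 951, and without the library labelled CHD3-KO replicate 2 they were 1247 and 1121. The F test over the 3 groups was passed by 3069 genes that differ among the 3 groups, by 1584 without SENP1-KO replicate 1 and by 1448 without SENP1-KO replicate 2.

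Of the 53 lists, 14 differed between the knockouts, and 0 did with an estimated correlation. The epithelial list had 8 of 11 members higher in SENP1-KO and the other 3 not past the test, also when adjusted over the list alone. Its median was 1.07 (camera adjusted p = 3.6e-07, adjusted p = 0.0964 with an estimated correlation, and 2.62e-08 at the lowest of its 22 alternatives). Pluripotency genes had 5 of 10 members higher, and 6 when adjusted over the list alone. Their median log2 change was 0.38 (camera adjusted p = 0.000132, adjusted p = 0.0964 with an estimated correlation, and 2.52e-06 at the lowest, which was given by fry). Ribosome biogenesis had 22 of 53 members higher, and 24 when adjusted over the list alone. The list median was 0.21 (camera adjusted p = 1.03e-05, adjusted p = 0.386 with an estimated correlation, and 8.95e-09 at the lowest). G1/S and DNA replication had 19 of 51 members higher, and 19 when adjusted over the list alone. The median log2 change was 0.22 (camera adjusted p = 5.29e-05, adjusted p = 0.412 with an estimated correlation, and 6.79e-08 at the lowest). Heat shock proteins and chaperones had 10 of 30 members higher (median 0.26, camera adjusted p = 0.00199, adjusted p = 0.425 with an estimated correlation, and 8.19e-05 at the lowest), among them HSPB1 (15.2 ± 5.87 against 5.37 ± 0.743 FPKM). Zinc finger genes had 74 of 371 members lower in SENP1-KO and 18 higher, with 72 and 17 when adjusted over the list alone. The median of the list was -0.16 (camera adjusted p = 0.00202, adjusted p = 0.458 with an estimated correlation, and 0.00136 at the lowest). Cell adhesion genes had 9 of 18 members higher and 2 lower (median 0.30, camera adjusted p = 0.0152, adjusted p = 0.425 with an estimated correlation, and 0.00156 at the lowest), with CADM1, a synaptic and epithelial adhesion molecule, at 8.81 ± 0.295 against 0.0289 ± 0.0231 FPKM. The other lists that passed were higher in SENP1-KO except antigen presentation. They were mitochondrial ribosomal proteins (camera adjusted p = 0.00398, adjusted p = 0.414 with an estimated correlation), fibroblast markers (0.00558 and 0.258), cytoskeletal genes (0.00558 and 0.425), metallothioneins (0.00582 and 0.425), glycolysis (0.0152 and 0.402), axon guidance (0.0274 and 0.386) and antigen presentation (0.0274 and 0.386). Axon guidance was at 0.0775, 0.0612 and 0.111 without SENP1-KO replicate 1, SENP1-KO replicate 2 and CHD3-KO replicate 3, within 0.000534 to 0.415 over all alternatives, at 0.293 with the GC trend removed and at 0.415 with a mean of at least 5 FPKM. Glycolysis was at 0.0917 with the GC trend removed and 0.0856 after quantile normalization, within 0.0024 to 0.402. Antigen presentation was at 0.0814 without SENP1-KO replicate 3, 0.111 without CHD3-KO replicate 1, 0.0884 with no filter and 0.0518 with a mean of at least 5 FPKM, within 0.000564 to 0.386. The lower ends of these 3 ranges (0.000534, 0.0024 and 0.000564) were given by fry, which does not compare a list with other genes. GC content moved with this comparison too (r = 0.34 and rho = 0.44 across genes). With the trend of GC content and length removed, 2475 of the 3627 genes were still called.

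Because both knockouts were set against the same control libraries, the overlap of their changes was set beside that of independent lists and of simulated unchanged groups. Genes near 0 in both knockouts led those that changed alike. TCEAL9, a gene on the X chromosome (103356489 to 103358462), fell from 28.5 ± 2.19 FPKM in control to 0.115 ± 0.0526 in SENP1-KO and 0.00960 ± 0.0166 in CHD3-KO (log2 changes -5.56 and -5.83, SE 0.14, limma adjusted p = 3.47e-08 and 5.46e-09). FASTKD2, which binds mitochondrial RNA and overlaps MDH1B on the opposite strand, fell from 8.41 ± 1.40 to 0.0569 FPKM in both (SD 0.00900 and 0.0623), and the collagen gene COL11A1 from 6.92 ± 0.801 to 0.0324 ± 0.0475 and 0.00394 ± 0.00366 FPKM. HCLS1, an actin regulator of blood cells, fell from 20.5 ± 2.24 to 1.43 ± 0.215 and 0.965 ± 0.197 FPKM, and AMBN, an enamel matrix gene, from 7.07 ± 2.06 to 0.478 ± 0.0654 and 0.373 ± 0.0721 FPKM. Other genes moved in opposite directions. TDGF1 was at 18.3 ± 2.26 FPKM in SENP1-KO and 1.504 ± 0.426 in CHD3-KO around 5.71 ± 0.779 in control, and the ephrin receptor EPHA7 at 13.7 ± 1.55 and 1.59 ± 0.426 around 5.77 ± 1.71. TNMD, a membrane protein of tendon cells, went the other way, from 95.7 ± 15.01 FPKM in control to 42.6 ± 4.30 in SENP1-KO and 203 ± 11.6 in CHD3-KO.

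Changes in the same direction were seen in 68 genes, where independent lists of this size would share 26.9: 23 were higher in both (18.9 for independent lists) and 45 lower in both (7.99). Opposite directions were seen in 96 genes against 25.4 for independent lists: 39 were higher in SENP1-KO and lower in CHD3-KO (15.97) and 57 the reverse (9.46). In 100 simulations of unchanged groups, controls included, a mean of 0.01 genes changed in the same direction and 0 in opposite directions. These simulations held no effects, so hardly any gene could pass in both comparisons, and they give no baseline for the counts of 68 and 96. Separate effects of the knockouts against shared controls were not simulated. Across genes the log2 changes of the knockouts correlated at r = 0.13, where the simulations with no effect gave 0.50. The share of genes with the same sign was 48.6%, against 66.66% simulated. Their covariance was 0.0224 against 0.0190 simulated, a difference of 0.00341. Genes with large changes in both knockouts, such as TCEAL9, weigh heavily in a covariance. The simulated values come from the shared controls alone, so they give no baseline for separate effects here either. The 3 control libraries could not be split, so part of the excess in the same direction may come from the shared controls. The count in the same direction was 22, 21 and 21 without control replicates 1, 2 and 3, and the count in opposite directions was 55 without control replicate 2, 54 without control replicate 3 and 63 without SENP1-KO replicate 2.

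**Figure D3:**
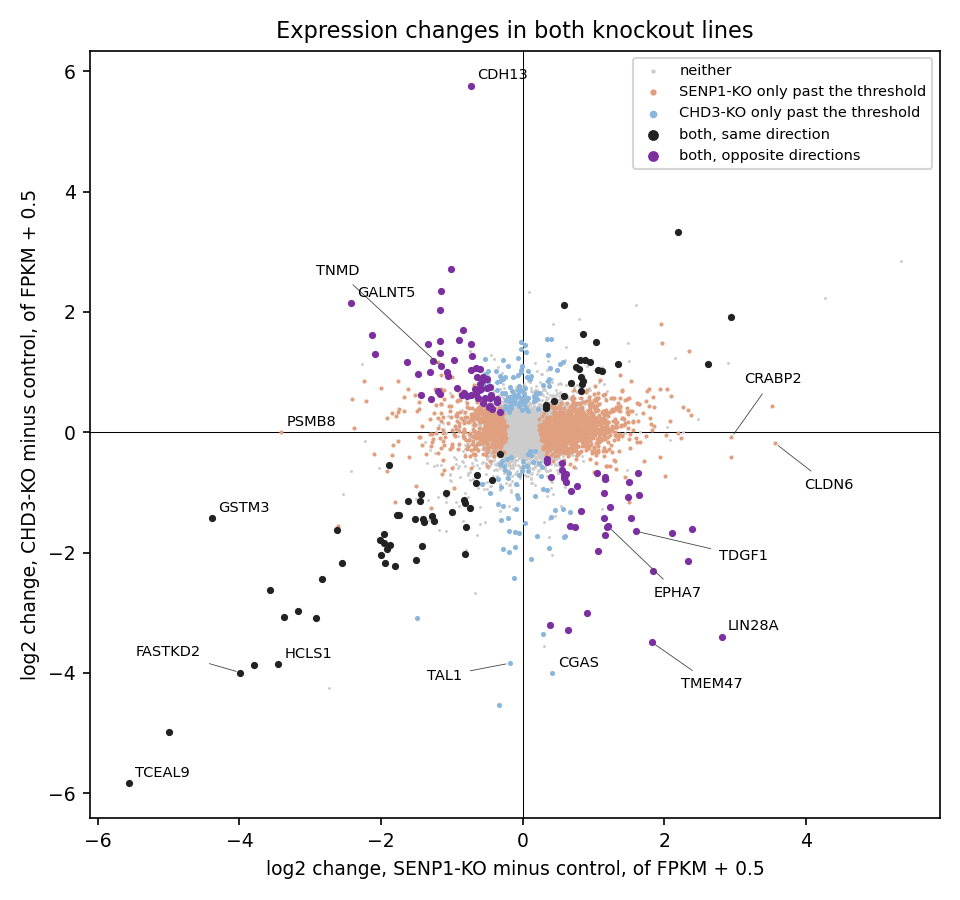
Log2 change of FPKM + 0.5 against control in SENP1-KO (horizontal) and CHD3-KO (vertical) for each tested gene except MT-ATP8, MT-ATP6 and MT-CO3, coloured by which comparison passed the limma test. The 68 genes changed in the same direction include TCEAL9 at -5.56 and -5.83, and the 96 changed in opposite directions include LIN28A at 2.82 and -3.40.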

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

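The tests of failed estimates, of the share of a transcript that overlaps another gene, of chromosome changes by size or in part of the cells, of a line difference that came before the editing and of mitochondrial RNA were chosen after the result was seen.

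The effects of the knockouts against control were compared with each other by the direct contrast of SENP1-KO with CHD3-KO, and these results differed between the knockouts. In total 96 genes changed in opposite directions (55 without control replicate 2, 54 without control replicate 3 and 63 without SENP1-KO replicate 2). LIN28A (6.21), TMEM47 (5.32), TDGF1 (3.24), PROM1 (2.95) and EPHA7 (2.77) were higher in SENP1-KO than in CHD3-KO on the log2 scale, and TNMD was lower (-2.25). The median log2 difference was 1.07 for the epithelial list and 0.38 for the pluripotency list. For both lists the adjusted p = 0.0964 with an estimated correlation. Groups of 3 libraries were not tested for single libraries that stand apart. SENP1-KO replicate 3 lay nearer to the control libraries (Pearson's r from 0.9715 to 0.9762) than SENP1-KO replicates 1 and 2 did (0.9625 to 0.9669).

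Sets of genes by chromosome moved in SENP1-KO against control: those on chromosomes 16, 19 and 22 were higher (camera adjusted p = 0.0141, 2.48e-05 and 0.00144) and those on 4 and 13 lower (0.029 and 0.000641). With the trend of GC content and transcript length removed from each library, 0 of the 5 chromosomes were still called by camera, and the median log2 change of chromosome 19 went from 0.20 to -0.01. A trend of GC content between libraries may therefore account for these sets. Gain or loss of these chromosomes in all cells was excluded by size, since the 5 medians lay between -0.12 and 0.20, while a whole copy more or less in a haploid or diploid line would move them by over 0.5. Of the 5 medians, 2 (19 and 13) lay outside the central 95% of random gene sets matched on GC content and length, by at most 0.0458 from the matched median. A gain or loss in part of the cells cannot be told apart there from a trend that the matching left over. Whether the trend came from the libraries or the SENP1 edit was not tested. Slopes with GC content also differed between libraries of the same group, at 0.06, -0.18 and -0.09 per 10 points in CHD3-KO.

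The genes COL11A1, FASTKD2, AMBN and TCEAL9 had group means of 5 FPKM or more in control and under 0.5 FPKM in both knockouts, where 0.0116 such genes would be shared by independent losses. Estimates that failed and were written as 0 in all knockout libraries were excluded, since 100% of these genes had a value above 0 in at least 1 of the 6. Single exact zeros remain in CHD3-KO: TCEAL9 in replicates 1 and 2, COL11A1 in replicate 2 and FASTKD2 in replicate 3. Whether the estimate failed in those libraries was not tested. Reads assigned to an overlapping gene instead were excluded in the annotation used here: AMBN and TCEAL9 overlap no gene, and for COL11A1 and FASTKD2 the overlap comes to at most 7.67% and 5.32% of the transcript length, too little to take nearly all reads (the test planned for this, on calls of the overlapping genes, was not used because none of them passed the filter). The 4 shared losses cannot be told apart from a difference between the control line and both knockout lines that came before the editing, because all 3 control libraries carry the same label. That difference and a shared effect of the edits both remain open, and the biological explanation was not tested.

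The mitochondrial genes MT-ATP8, MT-ATP6 and MT-CO3, which lie next to each other, were listed at 0 in all 3 CHD3-KO libraries. MT-ATP6 overlaps MT-ATP8 and MT-CO3 on the same strand, and MT-ATP6 and MT-CO3 have a near-identical copy, so their values are less certain. Whether reads were assigned to the copies was not tested. Loss of mitochondrial RNA as a whole was excluded, since the other 10 mitochondrially encoded protein genes had a median log2 change of 0.24 in CHD3-KO against control. An estimate that failed at this locus may account for the zeros, and it predicts that same median and values of exactly 0, seen in 9 of 9 cases. The zeros were what picked these genes out, and the median of 0.24 bears only on mitochondrial RNA as a whole. Neither can therefore decide whether the estimate failed.

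For the counts of changed genes and called lists between a pair of groups there are 10 splits of the 6 libraries, so the share of splits with a result as large cannot be under 0.05. The real split gave 2111 genes in SENP1-KO (highest other 0), 321 in CHD3-KO (highest other 2) and 3627 between the knockouts (highest other 1), with 1 of 10 splits as large in each. For lists the real values were 8, 13 and 14 and the highest others 6, 8 and 9, again with 1 of 10 as large. Over all 9 libraries 100 of the 280 splits were drawn. For the 3069 genes that differ among the 3 groups (highest other 2198), 1 of 100 splits was as large. This excludes only a chance assignment of the libraries to the 3 groups, and does not test how many of the 3069 calls are false. The counts in the same direction (68, highest other 62) and in opposite directions (96, highest other 0) also had 1 of 100 as large. Both counts depend on which group is the reference, which the 280 splits do not distinguish. Mixed splits also add differences between the lines to the spread, so chance was not excluded for these counts.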

How the results depend on the processing

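The alternatives that removed the trend with GC content and length, kept protein-coding genes only or left out genes listed at 0 in a whole group were chosen after seeing the data. Of 459 called results of named genes, 300 kept direction and call in all alternatives and 159 lost the call in at least 1; over all, 3 reversed. Read numbers are unknown, so what depth limits could not be given. No scaling moved the median of all genes by over 0.1. With no filter SENP1-KO had 928 higher genes, and 14 lists passed in SENP1-KO and 8 in CHD3-KO. At a mean FPKM of at least 5, with fewer genes tested, SENP1-KO had 900 higher and 437 lower genes, CHD3-KO 75 and 53, with 15 in the same and 47 in opposite directions and 7 lists in CHD3-KO. Quantile normalization gave 1058 lower genes in SENP1-KO. A fit over 6 libraries gave 109 higher genes in CHD3-KO, against 174 in the main fit. In SENP1-KO that fit gave more, 1669 higher genes against 1407, so fewer samples alone do not account for both. The main fit shares an estimate of the spread over the groups, while the median SD was 0.17 in CHD3-KO, 0.12 in SENP1-KO and 0.13 in control. With the GC and length trend removed, 243 genes were lower in CHD3-KO and 14 lists passed in SENP1-KO. The log2 changes of XRCC3, TRIM28 and GNAS in SENP1-KO then reversed to -0.0117, -0.18 and -0.0534. Exons of XRCC3 and GNAS overlap genes on the opposite strand. At an absolute log2 change of at least 1 there were 291 and 133 genes in SENP1-KO, 58 and 97 in CHD3-KO, 308 and 206 between the knockouts, 41 in the same and 31 in opposite directions, by construction fewer. With protein-coding genes only 4 lists passed in SENP1-KO. With an estimated correlation 0, 0 and 0 lists passed by camera in the 3 comparisons, where the preset correlation gave 8, 13 and 14, and with fry 22 passed in SENP1-KO and 32 between the knockouts. Unless construction is named, the cause was not tested. Without 1 library at a time, the ranges were 523 to 1619 higher and 293 to 818 lower in SENP1-KO, 77 to 145 and 71 to 131 in CHD3-KO, 1021 to 2175 and 951 to 1970 between the knockouts, 21 to 59 in the same and 54 to 97 in opposite directions, 1448 to 3583 genes that differ among the 3 groups, and 5 to 13, 11 to 15 and 12 to 19 lists. The lowest counts came without SENP1-KO replicate 2 (523, 293, 1021, 951 and 1448), control replicate 2 (77, 21 and 5 lists) and control replicate 3 (71, the same 21 and 54). Replicate numbers did not pair the libraries, since 3 of 9 correlated best with their own number.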

Other observations

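The scan of chromosomes for neighbouring genes and the test of a copy gain were chosen after the result was seen.

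Of 25 tested interferon-induced genes, 2 rose and 4 fell in SENP1-KO and 2 fell in CHD3-KO, and the list did not pass (camera adjusted p = 0.271 and 0.405). IFI16, a nuclear DNA sensor, fell from 1.45 ± 0.0289 FPKM in control to 0.00331 in SENP1-KO and 0.108 in CHD3-KO (log2 changes -1.95 and -1.69). The antiviral membrane protein BST2 rose in SENP1-KO from 45.5 to 88.3 FPKM (0.95, limma adjusted p = 0.00214). Among neuronal genes, of which 7 of 29 rose and 8 fell in SENP1-KO and 2 rose and 3 fell in CHD3-KO, the list did not pass (camera adjusted p = 0.112 and 0.596). The contact protein gene CNTN1 fell in SENP1-KO and CHD3-KO (-2.02 and -1.80). SYT11, a synaptotagmin, fell in SENP1-KO (-1.16) and rose in CHD3-KO (1.52). DPYSL3, a regulator of growth cones, fell from 4.84 ± 0.174 to 1.37 ± 0.132 and 1.47 ± 0.181 FPKM. Of 19 tested HOX genes 3 fell in SENP1-KO, among them HOXC8 (-0.69), and the list did not pass (camera adjusted p = 0.169). Of 29 tested p53 targets, 3 rose and 3 fell in SENP1-KO and 1 fell in CHD3-KO, and the list did not pass (camera adjusted p = 0.38 and 0.226). CDKN1A, a cell cycle inhibitor, fell in CHD3-KO from 2.72 to 0.879 FPKM (-1.22, SE 0.13). The apoptosis gene BAX rose in SENP1-KO from 16.8 to 38.1 FPKM (1.18, limma adjusted p = 0.00671). CDKN1A overlaps a gene on the opposite strand.

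Medians of 7 consecutive tested genes along the chromosomes were compared with 100 shuffles of gene order. In CHD3-KO against control 9 of 12765 windows lay above the highest shuffled median of 0.74, in 2 regions. The first lies on chromosome 17 (42609676 to 42980433, 370.8 kb), where 8 of 13 tested genes rose. EZH1, a histone methyltransferase, rose from 11.1 ± 1.32 to 29.9 ± 2.99 FPKM and BECN1, an autophagy regulator, from 28.8 ± 0.990 to 57.0 ± 10.5 FPKM. VPS25 (1.05) and PSME3 (0.49), chosen after their values were seen, lie in the region too. VPS25 rose in SENP1-KO as well (0.79, limma adjusted p = 0.00571), and BECN1 overlaps PSME3 on the opposite strand. The other region lies on chromosome 15 (40039311 to 40394246), where 3 of 8 tested genes rose. With the trend of GC content and length removed, the same 2 regions were found in CHD3-KO, and in SENP1-KO 1 region on chromosome 16 (56451490 to 56915850) holding the metallothionein genes.

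A hypothesis is that the CHD3-KO line gained a copy of the part of the chromosome 17 region from its first to its last called gene (42682613 to 42843758), which was drawn from the called genes themselves. In a near-haploid line a second copy may raise its genes by a like ratio. The called genes had ratios of CHD3-KO to control from 1.40 to 2.81 (median 2.201). Of the 10 tested genes of the segment, 2 did not pass: RAMP2-AS1 (log2 change 0.44) and HMGN2P15, which went the other way (-0.38). Of the genes of the segment below the filter, only those with values above 0 in all control and CHD3-KO libraries were taken. These 2 genes had a median ratio of 3.87. These were WNK4 (0.0815 to 0.317 FPKM) and CNTD1 (0.134 to 0.515 FPKM), which are near the floor and overlap COA3 and BECN1, genes that rose, so reads of those genes may enter their values. Joint regulation of neighbouring genes predicts the same, so the copy gain cannot be told apart from it without a measure of DNA.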
